A study of Mus musculus with 12 samples.

How the data were processed

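Bulk RNA-seq had been done on the cortex of mouse embryos at embryonic day 13.5, from matings of Med13l heterozygous mice, per the labels' protocols. Med13l encodes a subunit of the kinase module of Mediator, the complex that links transcription factors to RNA polymerase II. The labels gave 9 bulk libraries in 3 genotypes: wild type (WT), heterozygous (Het) and homozygous null (KO), with 3 brain tissues each. Single-cell samples of the 3 genotypes, each pooled from 5 embryos, were not analysed here.

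The deposited table held whole-number read counts for 55335 Ensembl mouse genes in the 9 bulk libraries, not normalised and with rows of 0 kept. The submitters' processing notes name FastQC 0.11.9, STAR 25.2b, StringTie 2.2.1, Cell Ranger 6.6.1 and Seurat for bulk and single-cell samples together, and the mouse genome build mm10. Which of them made the counts, the annotation release, the strand setting and the treatment of reads that map to several places were not given in the sources used here. Counts of overlapping genes, antisense genes and members of gene families with near-identical copies are therefore uncertain. A gene ID was paired with its symbol for 55154 of the 55335 IDs. Positions come from GENCODE M21 on GRCm38, the assembly that mm10 also names.

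Library totals ran from 37909377 to 52992392 counts. Genes were tested with edgeR 4.0.16 in R 4.3.3 by the quasi-likelihood F test, with TMM factors, the filterByExpr filter by genotype, robust dispersions and no covariate. All 9 libraries entered 1 fit, so that the genotypes shared an estimate of the spread. The filter kept 18844 genes, which held 99.95% of the counts, and the common biological coefficient of variation was 28.2%. P-values were adjusted by Benjamini-Hochberg within each comparison, and a gene was called at an adjusted p under 0.05. The comparisons were KO against WT, Het against WT, KO against Het and a linear slope over the number of functional alleles (2, 1 and 0). Standard errors of log2 fold changes were derived from the F statistic. CPM values used the TMM-scaled library sizes and are given as mean ± SD with n = 3 libraries.

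The design, the 31 gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The lists cover the Mediator modules, cell types of the embryonic forebrain, other cell types that a dissection can carry, and common signalling, cell cycle and stress programmes. They were tested with camera in limma 3.58.1 on voom values, two-sided, with a preset inter-gene correlation of 0.01, at least 5 tested members and Med13l left out. A list was called at an adjusted p under 0.05 over the 31 lists of a comparison. Medians of a list in the report are over edgeR log2 fold changes. List scores per library are mean log2 CPM of the members relative to the mean of all 9 libraries. Where a comparison called fewer than 10 genes, the rule named all of those, 5 further genes with the smallest unadjusted p as values and not as calls, and the 7 members of the Mediator kinase module. Members named as examples of a list, and Zfp932 and Mbtps2, were chosen after their values were seen.

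On simulated counts with known changes between KO and WT, the edgeR step on 18531 genes called 8% of 50 genes changed 1.5-fold, 52% of those changed 2-fold, 90% of those changed 4-fold and 96% of those changed 8-fold. Changes under 2-fold were thus mostly out of reach of this design. Each simulated gene was drawn independently with its own dispersion, without the spread that real libraries share across genes. These shares therefore do not measure how many larger changes the real fit misses. In that fit Yy2, at 1.72 CPM in WT and lower in KO by 25.9-fold, had an edgeR adjusted p = 0.391. The camera step, simulated for KO against WT on 18844 genes with independent members, called 10 of 10 lists shifted by 0.5 on the log2 scale and 0 of 20 unshifted lists.

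No pair of libraries in a group was a copy of the other: the lowest mean chi-square per gene of such a pair was 22.8. Pairs of different genotypes reached lower values, the lowest being 9.3 for Het 3 with KO 3, 16.8 for WT 1 with KO 3 and 19 for WT 1 with Het 3. The most alike libraries thus did not share a genotype. The labels name 3 brain tissues per genotype. Replicate numbers shared by the groups were not taken to pair the libraries. Alternatives were other size factors, other expression filters, DESeq2 1.42.0, limma-voom, a fit of 2 groups only, blocks for the replicate number and for the letter in the sample descriptions (D or F), embryo sex from Y-linked and Xist counts, other thresholds, removal of gene lists and leaving out each library. A fit without Het 1 and KO 1 and limma-voom with quality weights were added after the data had been seen. For the comparison of KO and Het effects, unchanged groups were simulated 20 times, with the simulated WT libraries shared by both comparisons. Every simulated library, the WT ones included, was drawn gene by gene around the WT mean with the SD of the WT libraries. Plots were drawn with matplotlib 3.10.9.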

Results

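The cortex of WT, Het and KO E13.5 mouse embryos was profiled by bulk RNA-seq, with 3 libraries per genotype. Totals were 44525713, 52992392 and 44290741 counts in WT, 44838473, 43469909 and 37909377 counts in Het, and 43686923, 38161494 and 43029920 counts in KO. Of the 55335 genes in the table, 24220 had no count in any library and 18844 were tested. The first principal component held 31% of the variance and set Het 1 (-69.4) apart from the other 8 libraries, which lay between -12.2 and 40.1. The second held 17.1% and followed the letter in the sample descriptions. On it WT 3, Het 3 and KO 3, the libraries of letter F, lay at -22.8, -31.4 and -30.1. Those of letter D lay between -9.52 and 31.9. By Y-linked and Xist counts, WT 1, Het 1, Het 3 and KO 3 came from female embryos and the other 5 from males.

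Med13l transcript was not lower in the libraries labelled KO or Het. Med13l (ENSMUSG00000018076, chromosome 5, 118560679 to 118765438) had 136 ± 16.9 CPM in WT, 153 ± 10.0 CPM in Het and 150 ± 17.5 CPM in KO (SD, n = 3). The log2 fold change was 0.14 (SE 0.12, 95% interval -0.13 to 0.41, edgeR adjusted p = 0.901) in KO against WT and 0.17 (SE 0.12, 95% interval -0.10 to 0.44, edgeR adjusted p = 0.999) in Het against WT. KO against Het gave -0.03 (SE 0.12, edgeR adjusted p = 0.948). A count over the whole gene does not see which part of it the null allele changes, so it does not check the genotype labels. The directions given from here on rest on the labels alone, and KO stands for the libraries labelled KO.

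The other members of the Mediator kinase module did not pass the test in any comparison either. Med13, the paralog of Med13l, had 171 ± 25.2 CPM in WT, 179 ± 22.2 CPM in Het and 169 ± 16.3 CPM in KO (SD, n = 3). Med12 had 152 ± 19.3, 158 ± 2.54 and 152 ± 7.05 CPM, and its paralog Med12l had 29.4 ± 6.31, 33.2 ± 7.01 and 33.1 ± 4.38 CPM. The kinases Cdk8 and Cdk19 had 74.6 ± 3.48 and 90.2 ± 5.94 CPM in WT against 80.0 ± 5.58 and 83.6 ± 5.60 CPM in KO, and their cyclin Ccnc had 31.5 ± 3.08 and 32.1 ± 3.29 CPM. Of the 7 genes, 0 passed the edgeR test in KO against WT, in Het against WT or in KO against Het. Of the 26 tested genes of the Mediator core, 0 were called in KO against WT, and the list had a median log2 fold change of 0.0035.

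**Figure D1:**
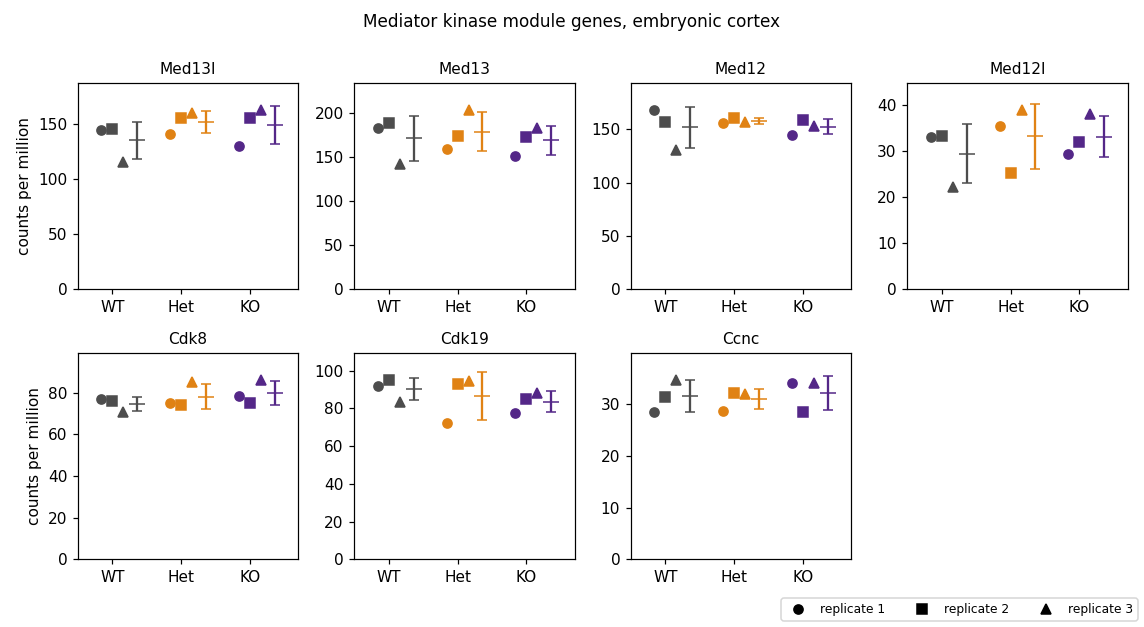
CPM (counts scaled by library size, vertical axes, from 0) of the 7 Mediator kinase module genes in WT, Het and KO libraries; points are libraries, with a marker shape per replicate number, and the line with bars is the mean and SD of 3 libraries. Med13l averages 136 CPM in WT, 153 CPM in Het and 150 CPM in KO.

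The comparison of KO with WT asked which genes differ when both Med13l alleles carry the null mutation. A single gene passed the test: Gm15446 (ENSMUSG00000090015, a protein-coding gene on chromosome 5, 109923400 to 109943936) fell by 4.24 on the log2 scale (SE 0.35, edgeR adjusted p = 0.0178). It had 19.1 ± 0.973 CPM in WT, 13.8 ± 3.98 CPM in Het and 1.00 ± 0.454 CPM in KO (SD, n = 3), with every KO library below every other library. Its locus lies 8.62 Mb from Med13l on the same chromosome. The nearby zinc finger gene Zfp932 (chromosome 5, 109996521 to 110010411) had 31.7 ± 3.84 CPM in WT and 23.6 ± 1.61 CPM in KO (edgeR adjusted p = 0.858). Of the 83 other sets of 3 libraries, 11 were separated at least as widely by some autosomal gene, with a floor of 0.1 CPM in the ratio. The fold change stayed between -4.63 and -3.97 when single libraries were left out, but the call was lost without WT 1 (adjusted p = 0.114), WT 2 (0.133), WT 3 (0.0814), Het 3 (0.0616) or KO 1 (0.271), with the description letter as a block (0.0629) and with embryo sex as a factor (0.0769). Within the letters D and F the difference in log2 CPM was -4.56 and -3.72, the letter F having 1 library per genotype.

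The 5 next genes by unadjusted p did not pass the edgeR test, and their values are given without a call. Yy2, a retroposed relative of the transcription factor gene Yy1 (chromosome X, 157566119 to 157568985), had 1.72 ± 1.03 CPM in WT, 0.523 ± 0.0527 CPM in Het and 0.0638 ± 0.0486 CPM in KO (edgeR adjusted p = 0.391). It lies inside Mbtps2 on the same strand, which had 50.9 ± 10.2 CPM in WT and 53.5 ± 4.42 CPM in KO, so reads of the 2 genes may not be fully separable. Unc5d, a netrin receptor of migrating cortical neurons (chromosome 8, 28646717 to 29219636), had 50.9 ± 6.73 CPM in WT and 28.2 ± 4.34 CPM in KO. Hrk, a pro-apoptotic BH3-only gene (chromosome 5, 118164648 to 118189478), had 10.4 ± 1.19 CPM in WT, 6.42 ± 0.168 CPM in Het and 5.73 ± 0.988 CPM in KO, and lies 0.371 Mb from Med13l. Mob3b (chromosome 4, 34949074 to 35157484) had 12.9 ± 1.23 and 19.7 ± 1.63 CPM, and Crabp2, a retinoic acid-binding protein gene (chromosome 3, 87948666 to 87953376), had 16.3 ± 2.03 and 30.7 ± 4.96 CPM. The last 4 had an edgeR adjusted p of 0.858 each. At an unadjusted p under 0.05 there were 1078 of 18844 genes, little more than the share of 0.05 that unchanged genes alone would give. The count depended on Het libraries, which share the estimate of the spread. It was 1826 without Het 1, 1084 without Het 2 and 937 without Het 3. DESeq2 called 18 genes, 9 higher and 9 lower, including all 6 genes named here, while limma-voom called 1, Gm15446.

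**Figure D2:**
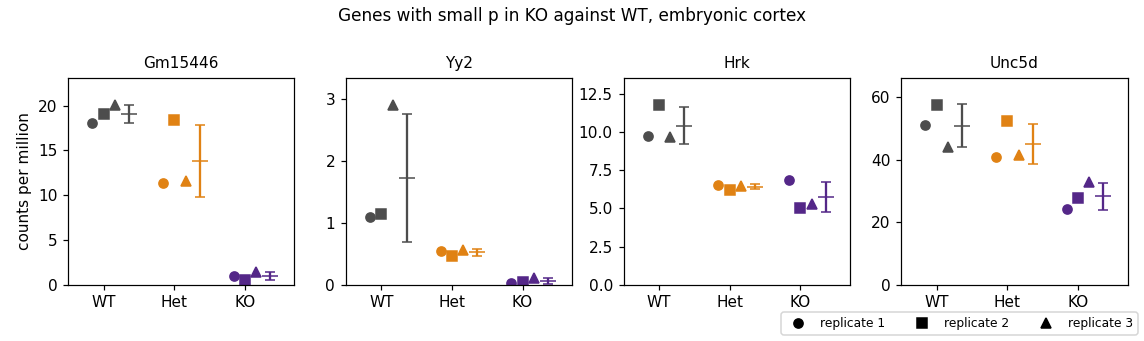
CPM (counts scaled by library size, vertical axes, from 0) of Gm15446, Yy2, Hrk and Unc5d in WT, Het and KO libraries; points are libraries, with a marker shape per replicate number, and the line with bars is the mean and SD of 3 libraries. Gm15446 averages 19.1 CPM in WT and 1.00 CPM in KO.

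Gene lists of erythroid, meningeal, endothelial and microglial cells stood higher in KO than in WT by camera with the preset correlation. With an estimated correlation they were not called, with an adjusted p = 0.336 for erythroid genes and adjusted p = 0.554 for each of the other 3. All 11 tested erythroid genes had a positive fold change (median 0.79, adjusted p = 1.86e-09), with the embryonic globin Hbb-y at 397 ± 66.9 CPM in WT and 745 ± 190 CPM in KO and Hba-a1 at 824 ± 115 and 1290 ± 243 CPM (SD, n = 3). All 16 meningeal and fibroblast genes were positive as well (median 0.70, adjusted p = 8.61e-09), with the collagen gene Col1a1 at 126 ± 24.7 and 261 ± 94.3 CPM and Lum at 54.3 ± 13.7 and 116 ± 51.9 CPM. Endothelial and mural genes (14 of 16 positive, median 0.56, adjusted p = 7.43e-06) and microglial genes (11 of 13 positive, median 0.39, adjusted p = 0.00255) went the same way. No member was called over all genes; adjusted over the list alone, 7 erythroid and 5 meningeal genes were higher, and 0 in the vascular and microglial lists.

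Scores on these lists differed between the libraries of a genotype. The meningeal score was 0.951 in KO 1 and 0.722 in KO 2 but -0.0581 in KO 3, against 0.174, 0.00429 and -0.608 in WT. The endothelial score was 0.750, 0.560 and -0.203 in KO, against 0.291, -0.000566 and -0.522 in WT. The erythroid score was 0.479, 0.748 and 0.103 in KO, against 0.0449, -0.482 and -0.226 in WT. On that list every KO library, KO 3 included, lay above every WT library. Within the description letters D and F, the KO scores lay above the WT scores on all 4 lists, by 0.747 and 0.55 for meningeal, 0.51 and 0.319 for endothelial, 0.347 and 0.154 for microglial and 0.832 and 0.329 for erythroid genes; letter F holds only WT 3, Het 3 and KO 3. Without KO 1, the microglial list was no longer called (adjusted p = 0.145) and the voom median of the meningeal list moved from 0.656 to 0.413. Without WT 3 the voom medians of the meningeal and endothelial lists moved to 0.415 and 0.309, from 0.656 and 0.552. Without KO 3 the microglial median moved from 0.355 to 0.535.

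The synapse, pan-neuronal, upper-layer, deep-layer and axon guidance lists stood lower in KO than in WT by camera with the preset correlation. With an estimated correlation they were not called: the deep-layer list had an adjusted p = 0.336 and the other 4 lists an adjusted p = 0.554. Of 22 synapse genes 21 were negative (median -0.44, adjusted p = 9.7e-09), and of 20 pan-neuronal genes 19 were negative (median -0.42, adjusted p = 5.07e-07). The glutamate receptor genes Gria1 and Gria2 had 73.2 ± 9.22 and 250 ± 20.9 CPM in WT against 37.2 ± 14.0 and 182 ± 40.7 CPM in KO, and neither passed the test. Upper-layer genes (10 of 12 negative, median -0.27, adjusted p = 0.0057), early and deep-layer projection neuron genes (12 of 16 negative, median -0.33, adjusted p = 0.0114) and axon guidance genes (17 of 25 negative, median -0.10, adjusted p = 0.017) were called as well. Adjusted over the list alone, Unc5d was lower in the upper-layer and axon guidance lists, and 0 genes in the synapse, pan-neuronal and deep-layer lists. KO 1 had a pan-neuronal score of -0.949, against -0.173 in KO 2 and 0.0446 in KO 3, where the meningeal scores were 0.951, 0.722 and -0.0581 and the endothelial scores 0.750, 0.560 and -0.203. Without KO 1 the voom median moved from -0.467 to -0.161 for pan-neuronal and from -0.477 to -0.232 for synapse genes, while the upper-layer (adjusted p = 0.157) and axon guidance (adjusted p = 0.234) calls were lost. The axon guidance call was also lost without WT 1 (adjusted p = 0.0694) or WT 2 (adjusted p = 0.124). Its voom median of -0.113 was -0.204 without WT 3, -0.265 without KO 2 and -0.192 without KO 3, and the upper-layer median moved from -0.362 to -0.645 without KO 3.

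The G2 and M phase, S phase, Notch and Wnt target lists stood higher in KO by camera with the preset correlation. With an estimated correlation they were not called, and the adjusted p was 0.779 for both cell cycle lists, 0.336 for Notch and 0.554 for Wnt targets. All 21 genes of the G2 and M phase list and all 20 of the S phase list were positive (medians 0.25 and 0.25, adjusted p = 0.000239 and 0.000615), and 0 members of either passed the gene test. All 16 Notch pathway genes were positive (median 0.17, adjusted p = 2.17e-05), with the receptor gene Notch3, which mural cells of vessels also express, at 98.4 ± 12.3 CPM in WT and 130 ± 13.7 CPM in KO, and 14 of 15 Wnt target genes were positive (median 0.40, adjusted p = 0.000239). The Wnt target score was 0.313 and 0.406 in KO 1 and KO 2, the libraries with meningeal scores of 0.951 and 0.722, but -0.169 in KO 3, within the WT range of -0.284 to -0.102. The Notch score was 0.302, 0.143 and 0.0898 in KO, against -0.0503, -0.0975 and -0.178 in WT. Without KO 1 the voom medians of the G2 and M phase and S phase lists moved from 0.247 and 0.243 to 0.152 and 0.153. In total 13 of 31 lists were called, 8 higher and 5 lower, against 0 with an estimated correlation. The other 18 lists, among them radial glia (adjusted p = 0.952) and intermediate progenitors (adjusted p = 0.164), were not called. In 5 of those 18 the median, the mean and the test differed in sign.

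**Figure D3:**
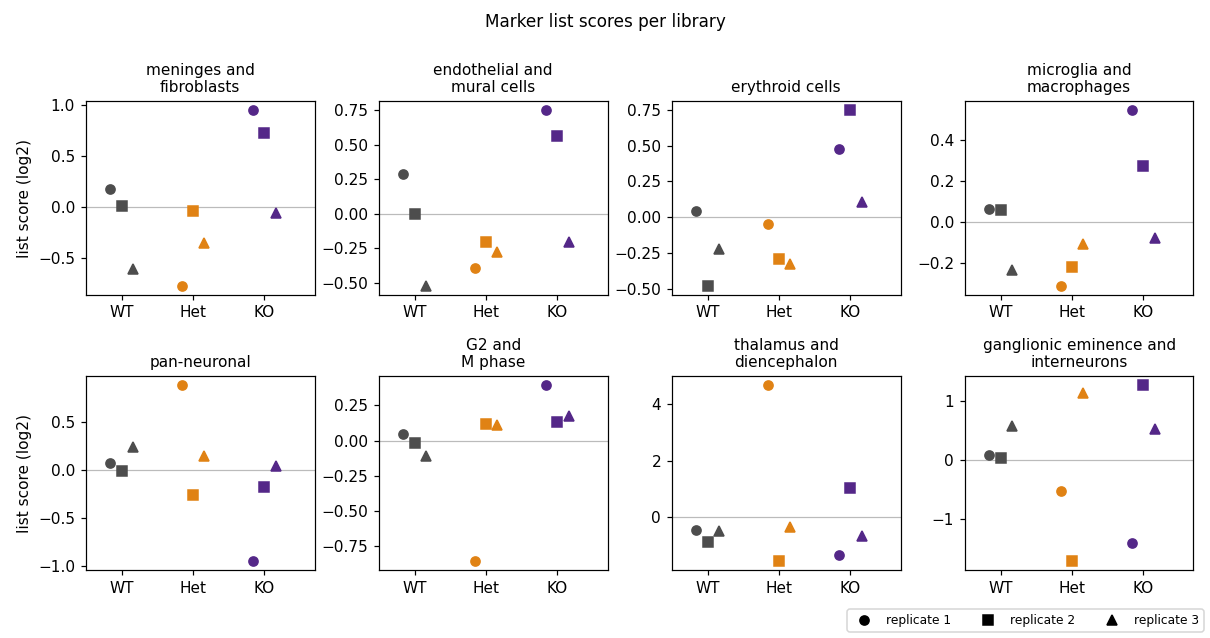
List scores per library (vertical axes, mean log2 CPM of the list's genes relative to the mean of the 9 libraries) for 8 marker lists in WT, Het and KO; each point is a library, with a marker shape per replicate number. KO 1 and KO 2 have the highest meningeal scores (0.951 and 0.722), and Het 1 has a thalamic score of 4.65.

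The comparison of Het with WT asked what follows from a null mutation of 1 allele. No gene passed the edgeR test. At an unadjusted p under 0.05 there were 294 of 18844 genes, fewer than the share of 0.05 that unchanged genes alone would give. DESeq2 called 1 gene, the mitochondrial tRNA gene mt-Tq, and limma-voom 0. Robo3, a receptor that controls axon crossing at the midline (chromosome 9, 37415669 to 37433246), had 9.86 ± 2.53 CPM in WT and 34.0 ± 21.7 CPM in Het (SD, n = 3), with 58.8 CPM in Het 1 and 19.2 and 23.9 CPM in Het 2 and Het 3. Its log2 fold change of 1.78 was 1.12 without Het 1, and that of H60b, with 1.32 CPM in Het 1, moved from 2.36 to 1.6. The other 4 of the 5 genes with the smallest p had under 1 CPM in both groups: H60b (0.140 ± 0.0245 and 0.730 ± 0.515), Trp63 (0.532 ± 0.0918 and 0.162 ± 0.0247), Gm9873 (0.0999 ± 0.0494 and 0.380 ± 0.0414) and Tspear (0.235 ± 0.0416 and 0.668 ± 0.185). All 5 had an edgeR adjusted p of 0.999 in Het against WT. In KO, Robo3 had 28.6 ± 4.71 CPM, with every KO library above every WT library. H60b, Gm9873 and Tspear had 0.550 ± 0.0437, 0.362 ± 0.0563 and 0.483 ± 0.0135 CPM in KO, also above WT, while Trp63 had 0.470 ± 0.145 CPM. The 5 genes were picked by their difference from the same WT libraries, so the KO values are no independent support.

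Genes of the thalamus and diencephalon were far higher in 1 Het library. Tcf7l2, a transcription factor of thalamic neurons, had 657 CPM in Het 1 and 17.2 and 22.4 CPM in Het 2 and Het 3, against 14.3 to 16.6 CPM in WT. Of the 13 tested genes of this list 11 were highest in Het 1, and the list was called in Het against WT (median 3.90, adjusted p = 0.0139; adjusted p = 0.749 with an estimated correlation), with 8 genes higher adjusted over the list alone. Without Het 1 its adjusted p was 0.921. Het 1 also had the lowest G2 and M phase score (-0.857) and the highest pan-neuronal score (0.883).

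The cholesterol synthesis list was called higher in Het (17 of 18 positive, median 0.08, adjusted p = 0.00015). Lower in Het were ribosomal protein genes (40 of 41 negative, median -0.11, adjusted p = 1.42e-07), S phase (adjusted p = 0.00116) and G2 and M phase genes (adjusted p = 0.00133), immediate early genes (0.011), ganglionic eminence genes (0.0139), radial glia (0.0198), endothelial (0.0198), meningeal (0.0198) and microglial genes (0.022). For ganglionic eminence genes the test was negative while the edgeR median was 0.06. Each of these had an adjusted p = 0.749 with an estimated correlation. The ribosomal protein voom median of -0.118 was -0.0279 without Het 1 (adjusted p = 0.417), -0.061 without WT 3 and -0.223 without Het 2. The cholesterol synthesis call was lost without Het 1 (adjusted p = 0.0851), though its voom median of 0.0783 was then 0.0768, and the median was 0.123 without WT 2 and 0.118 without Het 3. Of the 11 called lists, 1, the ganglionic eminence list, was also called in the same direction without Het 1, when 5 lists in all were called, and the S phase and G2 and M phase lists then stood higher in Het (voom medians 0.107 and 0.132). Without WT 2, 7 lists were called in all, and the endothelial (adjusted p = 0.177), meningeal (0.215), microglial (0.177), radial glia (0.153) and thalamic (0.214) lists were not. The endothelial (0.707), meningeal (0.46) and microglial (0.188) calls were also lost without WT 1, the ganglionic eminence call without WT 3 (0.118) or Het 2 (0.379), the microglial call without Het 2 (0.16) and the endothelial call without Het 3 (0.055).

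KO against Het tested the difference between the 2 mutant genotypes directly. Gm15446 was again the only call and fell by 3.77 on the log2 scale (SE 0.34, edgeR adjusted p = 0.0407). At an unadjusted p under 0.05 there were 1459 of 18844 genes, while the 10 splits of the same libraries ranged from 303 to 3235. Spry4, an inhibitor of receptor tyrosine kinase signalling (chromosome 18, 38586247 to 38601415), had 4.59 ± 0.324 CPM in Het and 10.0 ± 1.85 CPM in KO (SD, n = 3). Gxylt2 (chromosome 6, 100704734 to 100810913) had 5.76 ± 0.442 and 12.6 ± 2.84 CPM, Hbb-y (chromosome 7, 103851749 to 103853216) 372 ± 48.7 and 745 ± 190 CPM, and Marveld1 (chromosome 19, 42147400 to 42151703) 14.0 ± 1.5 and 22.6 ± 3.67 CPM. Trim17 (chromosome 11, 58954685 to 58973098) had 2.19 ± 0.549 and 0.826 ± 0.164 CPM. These 5 had an edgeR adjusted p of 0.607 each, and DESeq2 called them among 24 genes, 18 higher and 6 lower. The Gm15446 call was lost by limma-voom (adjusted p = 0.0775), in a fit of the 2 groups alone (0.752), with the description letter (0.131) or sex (0.158) in the model, and when any library other than KO 3 was left out (0.0547 to 0.544). The fold change stayed between -4.16 and -3.5 on the log2 scale when single libraries were left out.

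Of the 31 lists 14 were called between KO and Het, 10 higher and 4 lower in KO, and 0 with an estimated correlation (smallest adjusted p = 0.483). Meningeal (16 of 16 positive, median 0.97, adjusted p = 3.68e-11), endothelial (16 of 16 positive, median 0.72, adjusted p = 1.66e-08) and erythroid genes (11 of 11 positive, median 0.54, adjusted p = 9.57e-08) were higher in KO, with 9, 8 and 6 genes higher adjusted over the list alone. Pan-neuronal genes were lower (20 of 20 negative, median -0.65, adjusted p = 1.51e-08), as were the synapse, cholesterol synthesis and mitochondrially encoded lists, and the microglial, S phase, G2 and M phase, Notch, immediate early, hypoxia and ribosomal protein lists were higher. Without Het 1 the voom median of the G2 and M phase list moved from 0.446 to 0.126, of the S phase list from 0.408 to 0.11, and of the pan-neuronal list from -0.597 to -0.269, against -0.294 without KO 1. Without Het 1 the Notch median also moved from 0.28 to 0.0638 and the synapse median from -0.534 to -0.265, and without KO 1 to 0.183 and -0.263. The ribosomal protein, hypoxia, cholesterol synthesis, immediate early and mitochondrially encoded calls were lost without Het 1 (adjusted p = 0.79, 0.208, 0.516, 0.304 and 0.0753). Their voom medians were then -0.00254, 0.056, -0.0321, 0.194 and -0.0852, from 0.104, 0.171, -0.0827, 0.307 and -0.0804, so that the mitochondrially encoded median did not shrink. Ribosomal protein (0.73) and hypoxia (0.289) calls were lost without KO 1, the hypoxia call without Het 3 (0.0504), the cholesterol synthesis call without Het 2 (0.0865) or KO 3 (0.287), and the mitochondrially encoded call without Het 2 (0.0518), KO 2 (0.176) or KO 3 (0.0692). Without Het 1 and KO 1 together, the pan-neuronal list had an adjusted p = 0.442 and the G2 and M phase list an adjusted p = 0.176, while the meningeal list had an adjusted p = 2.95e-07. The meningeal voom median was then 0.515, from 0.956. Of the 14 called lists, 5 were also called in the same direction in that fit.

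The slope over the number of functional alleles asked which genes change stepwise with allele dose. No gene passed the edgeR test. At an unadjusted p under 0.05 there were 1032 of 18844 genes, near the share of 0.05 that unchanged genes alone would give, and 2100 without Het 1. By limma-voom 0 genes were called and by DESeq2 10, among them Gm15446, Yy2, Hrk and Unc5d.

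The KO and Het fold changes against WT were compared over 18844 genes. Their covariance was 0.0488, below the 0.0709 of simulated unchanged groups that shared 3 simulated WT libraries. Pearson's r across genes was 0.322 against 0.504 simulated, and 55.1% of genes had the same sign against 66.7% simulated. The simulation gave all 3 groups the WT spread. Het 1 differed from Het 2 and Het 3 by a mean chi-square per gene of 164 and 101. Het 2 and Het 3 differed by 34.8, KO pairs by 35.9 to 67.6 and WT pairs by 22.8 to 49.5. A wider spread in Het or KO lowers r and the shared signs by itself, so the gaps in r and in signs are not read as less agreement. That spread does not by itself lower the covariance, whose gap it leaves unexplained. The simulated covariance had an SD of 0.0049, but each simulated gene was drawn on its own. This SD thus leaves out spread that libraries share across genes, and the covariance gap is not read as less agreement either. Genes are not independent replicates, and the 3 WT libraries were too few to split. Without Het 1, the covariance was 0.0705 against 0.0727 simulated and r was 0.426 against 0.440 simulated. The share with the same sign then turned to 67.5% against 64.8% simulated. Without Het 1 and KO 1 the share was 67.7% against 63.1% simulated.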

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

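Fits without Het 1 and KO 1 and limma-voom with quality weights were chosen after the data had been seen; the other alternatives were planned. Other size factors, other expression filters, removal of the erythroid, mitochondrial and sex genes, an adjusted p under 0.1 and an absolute log2 fold change of at least 1 left all 4 counts of called genes as they were (1 in KO against WT, 0 in Het against WT, 1 in KO against Het and 0 for the slope). DESeq2 called 18, 1, 24 and 10 genes, in that order. Outside chromosome 5, which carries Med13l and Gm15446, 0 genes were called in KO against WT and 0 in KO against Het. With the description letter as a block, with embryo sex as a factor and without Het 1 and KO 1, both counts fell from 1 to 0. KO against Het also went to 0 by limma-voom, by limma-voom with quality weights and in the fit of 2 groups only. Leaving out 1 library gave 0 to 1 genes in KO against WT, in KO against Het 0 to 1, and 0 in the remaining 2 comparisons. The causes were not tested, except that a fit without a library has fewer samples. At 3 libraries per genotype and at least 37909377 counts per library, no fit at another depth was made, so what depth limits was not measured.

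Replicate numbers were not taken to pair the libraries, since the labels name no pairing. The counts do not settle whether they do. Of 9 pairs with the same number, 4 had a correlation of deviations over 0.1 (range -0.27 to 0.27). Among libraries of other genotypes, 5 of 9 libraries matched their own number best. No level for unpaired libraries was set beside these values. The 3 pairs of number 3, which all carry the letter F, had correlations of 0.082, 0.15 and 0.27, so a shared origin of those libraries stays open. With the replicate block, 0 genes were called in KO against WT and 0 in KO against Het, with Gm15446 at log2 fold changes of -4.26 and -3.79.

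With an estimated correlation, 0 lists were called in KO against WT, 0 in Het against WT and 0 in KO against Het. Without Het 1 and KO 1, 6 lists were called in Het against WT. Leaving out 1 library gave 13 to 15 lists in KO against WT, 5 to 14 in Het against WT and 13 to 17 in KO against Het. List medians here are over voom values. In Het against WT, leaving out 1 library moved the median over -0.194 to 0.063 for radial glia, -1.18 to 0.181 for ganglionic eminence genes, -0.346 to 0.107 for S phase and -0.379 to 0.132 for G2 and M phase; without Het 1 and KO 1 the values were 0.0631 for radial glia, 0.107 for S phase and 0.131 for G2 and M phase. In KO against Het, ribosomal protein genes ranged from -0.006 to 0.199 and were -0.0947 without Het 1 and KO 1, where hypoxia genes were -0.0347. Of the values for single called lists under alternatives, 498 kept direction and call, 99 lost the call and 11 changed direction; the cause was not tested.

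The covariance of KO and Het effects minus its simulated value was -0.0221. It was -0.0309 by limma-voom and -0.0117 without Het 1 and KO 1, and ranged from -0.0347 to -0.00226 when 1 library was left out.

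Among single genes, 46 values changed sign, all of Mediator kinase module genes not called in either fit, and the cause was not tested. Values are log2 fold changes, with the range over fits without single libraries in parentheses. Med13l in KO against Het was 0.00161 with total counts only, 0.000576 with sex and 0.00778 without Het 1 and KO 1, and ranged from -0.0979 to 0.0549 without single libraries. In KO against WT, Med12 was -0.00968 with no expression filter and -0.0441 with quality weights (-0.0908 to 0.0802 without single libraries), Ccnc -0.0198 without Het 1 and KO 1 (-0.0411 to 0.113) and Med13 0.05 (-0.133 to 0.0533). In Het against WT, Med12 was -0.0127 with quality weights (-0.0352 to 0.135), Ccnc 0.0208 without Het 1 and KO 1 and 0.0721 with quality weights (-0.0936 to 0.0549), Cdk19 0.0522 and 0.0105 (-0.128 to 0.0522) and Med13 ranged over -0.046 to 0.14. In KO against Het, Cdk8 was -0.0473 with quality weights (-0.0256 to 0.0922), Ccnc -0.0406 without Het 1 and KO 1 and -0.0221 with quality weights, and Med12l 0.0277 with total counts only, 0.0177 by limma-voom, 0.00423 with the replicate block, 0.132 with sex and 0.121 without Het 1 and KO 1 (-0.163 to 0.119); Med13 ranged over -0.163 to 0.0131 and Cdk19 over -0.17 to 0.0154. Med13l stayed positive without single libraries, at 0.0426 to 0.226 in KO against WT and 0.0757 to 0.222 in Het against WT.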

Other observations

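The tests of explanations in this part were chosen after the results they bear on had been seen. Ganglionic eminence and interneuron genes varied widely between libraries of Het and of KO. Dlx2, a transcription factor of ventral forebrain progenitors, had 25.5, 25.5 and 30.1 CPM in WT, 2.19, 4.70 and 57.5 CPM in Het, and 9.60, 59.2 and 36.4 CPM in KO. The list score was lowest in Het 2 (-1.71) and KO 1 (-1.41) and highest in KO 2 (1.27) and Het 3 (1.14). KO 2 also had 63.3 CPM of the thalamic gene Tcf7l2, against 14.3 to 22.4 CPM in the libraries other than Het 1. Cajal-Retzius genes had a score of 1.52 in Het 1 and at most 0.0384 in the other libraries. The members of this list did not move together. Lhx1 and Ebf3 had 46 ± 63.2 and 152 ± 223 CPM in Het, against 8.84 ± 1.2 and 25.6 ± 2.61 CPM in KO. Trp73, Calb2 and Ndnf had 26.6 ± 10.3, 9.64 ± 4.28 and 5.7 ± 2.81 CPM in Het. Of the 11 members, 8 were lower in KO than in Het and these 3 were not, so the score is not read as more Cajal-Retzius cells.

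Several genes were on in some libraries and near 0 in others without regard to genotype. The zinc finger gene Zfp990 (chromosome 4, 145510759 to 145539188) had 4.87, 5.11 and 6.70 CPM in WT 2, Het 1 and KO 1 and at most 0.13 CPM in the other 6. Gm45062 (chromosome 6, 8259450 to 8597480) had 7.48, 5.59 and 14.1 CPM in WT 1, Het 3 and KO 3 and 0 CPM elsewhere. The antisense gene BC023719 (chromosome 17, 36111426 to 36117121) had 10.1, 8.34 and 7.29 CPM in WT 3, Het 3 and KO 3, the libraries of letter F. It had at most 0.0223 CPM in the other libraries. Y-linked genes had 20 counts in WT 1 and 60 in KO 3, 0.181% and 0.562% of the male mean, and 0 in the other 2 female libraries.

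Splits of the same libraries give a measure of what regrouping alone produces. Each comparison of 3 with 3 libraries has 10 splits, too few for a share under 0.05. In KO against WT the real split called 1 gene and the highest other split 2, with 4 of the 10 calling as many as the real one. In KO against Het the real split called 1 and the highest other 1 (2 of 10). For lists the real splits called 13, 11 and 14 in KO against WT, Het against WT and KO against Het, and the highest others 16, 15 and 19, with 3, 7 and 3 of 10 splits at least as high. The split of KO and Het libraries by embryo sex (Het 1, Het 3 and KO 3 against the rest) called 1 gene and 15 lists. With sex in the model the real comparison called 0 genes, though the log2 fold change of Gm15446 stayed at -3.77. Its edgeR adjusted p was then 0.158, from 0.0407. In Het against WT and for the slope the real count was 0, so 10 of 10 splits and 40 of 40 drawn orders reach it by construction and say nothing about chance; the highest other counts were 3 and 2.

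Med13l was not lower in the libraries labelled KO. A mix-up of libraries was looked at through all 84 ways to pick 3 of the 9 libraries, by the autosomal gene that parts them most widely. The gap was the lowest CPM of one side over the highest of the other, with a floor of 0.1 CPM for the latter. The KO set ranked 12 of 84, with a gap of 7.65-fold for Gm15446. The highest other gap, 196-fold, came from the rRNA gene CT010467.1. It had 19.6 to 22.5 CPM in WT 3, KO 1 and KO 3 and 0 CPM elsewhere, so that its size rests on the floor. This measure does not single the KO libraries out, and a mix-up cannot be told apart from correct labels. A null allele that leaves most of the transcript in place may also give these values: the lower 95% bound of the log2 fold change was -0.129. Counts per exon, which would part the 2, were not used here.

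Gm15446 was lower in KO, and DNA linked to the targeted allele on chromosome 5 is a candidate explanation. With Gm15446 left out, the 25 Mb on each side of Med13l held 1 of the 20 genes with the smallest p, and 0.51 of the same-size runs of autosomal genes held as many. Over 4 window sizes and 2 statistics, 0 of 8 such shares were under 0.05 (lowest 0.0678), which leaves linkage of Gm15446 itself open. Background variants that differ among the embryos may be another source: 11 of the 83 other sets of 3 libraries were parted at least as widely by some gene. An effect of the null allele on Gm15446 stays open too.

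Meningeal, vascular, microglial and erythroid lists were higher in KO by camera with the preset correlation, but not called with an estimated one (adjusted p = 0.336 for erythroid genes and 0.554 for the other 3). A candidate explanation is more meningeal, vascular and blood tissue in single dissections. KO 3 lay within the WT range on 3 of the 4 lists, while KO 1 and KO 2 lay above every WT library on all 4. The exception for KO 3 was the erythroid list, where its score of 0.103 lay above the highest WT score of 0.0449. KO 3 lay above WT 3, the WT library of its letter F, on 4 of 4 lists. WT 3, however, had the lowest WT score for meningeal (-0.608), endothelial (-0.522) and microglial genes (-0.232). Het 3 also lay above WT 3 on these lists, by 0.249, 0.248 and 0.126, but not for erythroid genes (-0.101). KO lay above WT on 4 of 4 lists within letter D, but its KO libraries are KO 1 and KO 2. The difference within letter D therefore does not weigh against uneven dissections. All 16 meningeal and all 11 erythroid genes had a positive fold change. KO and WT libraries did not overlap in 3 of the 16 and in 5 of the 11. Among the latter, Hba-a1 had 1420, 1430 and 1010 CPM in KO against 927, 699 and 846 CPM in WT. Other abundant members overlapped. Col3a1 had 994, 810 and 407 CPM in KO against 511, 410 and 232 CPM in WT, and Hbb-bs 577, 852 and 533 CPM against 583, 363 and 504 CPM. With 1 library per genotype in letter F, uneven dissections and a difference of genotype in these tissues cannot be told apart.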
